A study of Homo sapiens with 48 samples.

How the data were processed

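Gene expression was measured by RNA sequencing in 2 human breast cancer cell lines, MDA-MB-231 and MCF-7, after transfection with 1 of 4 small interfering RNAs (siRNAs). They were a universal negative control (siControl), an siRNA against all BRD4 transcripts (siPan), and siRNAs against the long (siL) and the short (siS) isoform. Each line had 3 libraries per siRNA, 12 per line and 24 in all. Per the labels, cells were transfected 2 times for 48 h each, and libraries were made with a stranded total RNA kit from 1 µg of DNase-treated, rRNA-depleted total RNA with a RIN of at least 9. The other 24 samples of the series, chromatin profiles, were not analysed here. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

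The submitters' processing notes name FastQC 0.11.2, TopHat2 2.0.12, Picard 1.127, featureCounts, Subread and edgeR, and the genome build hg19. The strand setting used in counting is not given in the sources used here. The deposited signal values, 1 table per line, are normalized CPM: gene counts divided by an effective library size, so that the columns have different totals, above the plain CPM total in some libraries. Dividing each column by its smallest positive value gave whole numbers for every value within a tolerance of 0.1, and these were used as recovered reads. The design, written before the data were examined, had assumed plain CPM. The test it chose was kept, and rescaling every library to the same total was tried as an alternative. Both tables give gene symbols only, 20074 in the MDA-MB-231 table and 22342 in the MCF-7 table. The gene table at hand was for GRCh38, so no coordinates are given. Dates had replaced 28 symbols of the MDA-MB-231 table, and these were never named. No per-sample column was left unused (0 columns). The tables were normalized separately, so levels were not compared between them, and only fold changes taken within a table were.

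Recovered reads ranged from 14490015 to 20108461 per library in MDA-MB-231 (median 19089690.5) and from 2661108 to 12616147 in MCF-7 (median 6669646.5). A gene listed at 0 can have had up to 3 reads by counting error alone, which is 0.1366 to 0.212 CPM in MDA-MB-231 and 0.226 to 0.957 CPM in MCF-7. These floors cover counting error only.

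Genes with at least 1 CPM in at least 3 of the 12 libraries of a line were tested, 13187 in MDA-MB-231 and 13818 in MCF-7. log2(CPM + 1) was fitted with limma-trend, with the 4 groups in 1 fit per line. Each knockdown was compared with siControl, and siL with siS. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale. For the 11914 genes tested in both lines, the difference between the 2 log2 fold changes was divided by its combined standard error. Gene lists (47 written, of which 46 had the 3 tested members needed in at least 1 line) were written before the data were examined and tested with camera at a preset correlation of 0.01. The called lists were tested again with an estimated correlation. Members were also counted when adjusted over the list alone. Lists of extracellular matrix (ECM) genes were included because the theme of the study was known, so they are not independent evidence.

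In the fits without a library-set term (described below), named genes followed a rule fixed before the data were examined. For each knockdown against siControl it names the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in 1 of the groups, and with all 3 knockdown libraries on 1 side of all 3 control libraries. For siL against siS and for the differences between lines it names the 5 largest in each direction. BRD4, BRD2, BRD3, EN1, MYC and HEXIM1 were always named. For each list it names up to 4 called members with the largest change. Small RNA, antisense and LOC symbols were left out of these rankings. For the fit with the library-set term, added after the data were seen, the condition on all 3 libraries was replaced by the sign of the fold change. Genes named from that fit, such as those after siPan and siS in MCF-7, did not have to meet it.

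Alternatives were pseudocounts of 0.25 and 2, no filter or a filter at 5 CPM, rescaling by TMM factors or to the same total, quantile normalization, fits of only the 6 libraries compared, the replicate number as a term, edgeR, DESeq2 and robust limma on the same values or recovered reads, fry in place of camera, 1 fit over all 24 libraries, and the removal of each library in turn. Whether the replicate numbers pair libraries was checked by the correlation of deviations from the group mean, with pairs taken as such where every same-numbered pair exceeded 0.1: siControl with siL in MDA-MB-231 (0.535 to 0.934) and siControl with siPan in MCF-7 (0.528 to 0.854). After the data were seen, a term for 2 sets of libraries per line was added. The sets were parted at the widest gap of the first principal component, and the term was also tried with edgeR, with the filter at 5 CPM and within each set. A fit with 1 surrogate variable was added at the same stage. The shared use of the 3 control libraries was looked at with 100 simulated draws in which no group was changed.

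The main test was tested on simulated data with the spread and the library sets of the real libraries. Each of 5 draws had 200 changed genes, taken from genes with a mean of at least 5 CPM. The shares found need not hold for genes of lower level. With siPan in MDA-MB-231 the main test found 36.1% of 4-fold and 1.19% of 2-fold changes, and with the library-set term 99.4% and 49.3%. In MCF-7 these shares were 74.8% and 10.4%, and 100% and 86% with the term. Between 4.82% and 6.63% of the calls were false with the term, over the 3 knockdowns and both lines, and 0% without it. The simulated libraries held exactly 2 sets with independent noise in each gene, which is what the term assumes. Real scores on the first principal component were graded within a set, from 10.4 for siPan 1 to 106.9 for siControl 3 in MDA-MB-231. The shares of false calls therefore need not hold for the real libraries. The comparison of siL with siS was not simulated. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.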

Results

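RNA was sequenced from MDA-MB-231, a triple negative breast cancer cell line, and from MCF-7, a second breast cancer line, after siRNA knockdown of BRD4, a bromodomain protein that binds acetylated chromatin. The study asks whether the long and the short BRD4 isoform act in opposite ways. Each line had 3 libraries with siControl, 3 with siPan, 3 with siL and 3 with siS. Recovered reads in MDA-MB-231, in the order of replicates 1, 2 and 3, were 19431884, 20108461 and 14490015 with siControl, 19934184, 17495664 and 19908178 with siPan, 19404886, 18549177 and 19900641 with siL, and 18084614, 18774495 and 16749116 with siS. In MCF-7 they were 12243772, 6005718 and 5266808 with siControl, 12616147, 4829101 and 5432174 with siPan, 9321445, 7333575 and 2661108 with siL, and 9035249, 5683627 and 7680097 with siS. Levels are deposited normalized CPM as mean ± SD with n = 3, fold changes are log2 against siControl, and adjusted p-values are from limma.

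BRD4 mRNA in MDA-MB-231 was 37.3, 30.2 and 29.1 CPM in the siControl libraries, 17.8, 21.8 and 23 with siPan, 29.9, 21.5 and 20.8 with siL, and 21.3, 11.6 and 22.3 with siS. The BRD4 fold change was -0.60 after siPan (SE 0.28, adjusted p = 0.287), -0.41 after siL (adjusted p = 0.745) and -0.82 after siS (adjusted p = 0.115), so no fall passed the test with limma, although every siPan and siS value lay below every siControl value. The siS fall of BRD4 passed without siControl 3 (adjusted p = 0.0369), with DESeq2 (0.0469) and with a surrogate variable (0.0113; range over all alternatives 0.0113 to 0.346), and the siPan fall with a surrogate variable (0.0375; 0.0375 to 0.537). BRD4 in MCF-7 was 20.9, 58.0 and 63.7 CPM with siControl, 8.99, 48.5 and 34.6 with siPan, 32.4, 14.6 and 80.4 with siL, and 66.1, 64.9 and 67.1 with siS. There the BRD4 fold changes were -0.75 (SE 0.65, adjusted p = 0.672), -0.33 (adjusted p = 0.933) and 0.62 (adjusted p = 0.661), and only the siPan fall passed with a library-set term (SE 0.22, adjusted p = 0.0498). With that term the siPan value stayed at -0.75, while the siL value turned to 0.27 and the siS value went to 0.02. Gene-level counts cannot separate the BRD4 isoforms. The related genes BRD2 and BRD3 were called in no comparison with limma without further terms. After siS in MCF-7 both passed with a surrogate variable (adjusted p = 0.03 and 0.0245; ranges over all alternatives 0.03 to 0.819 and 0.0245 to 0.799) and BRD3 also with the library-set term and a filter at 5 CPM (0.0446). Between siL and siS in MCF-7 BRD2 passed without siL 3 (0.0476, range to 0.385), and their difference between lines after siS passed under some alternatives (BRD2 0.0141 to 0.471, BRD3 0.0023 to 0.313), both of them without siControl 3 of MDA-MB-231 (0.0266 and 0.035). EN1, which encodes a homeobox protein, had 0 reads in the 12 MDA-MB-231 libraries and at most 0.515 CPM in MCF-7, within the limit that 3 reads allow.

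**Figure D1:**
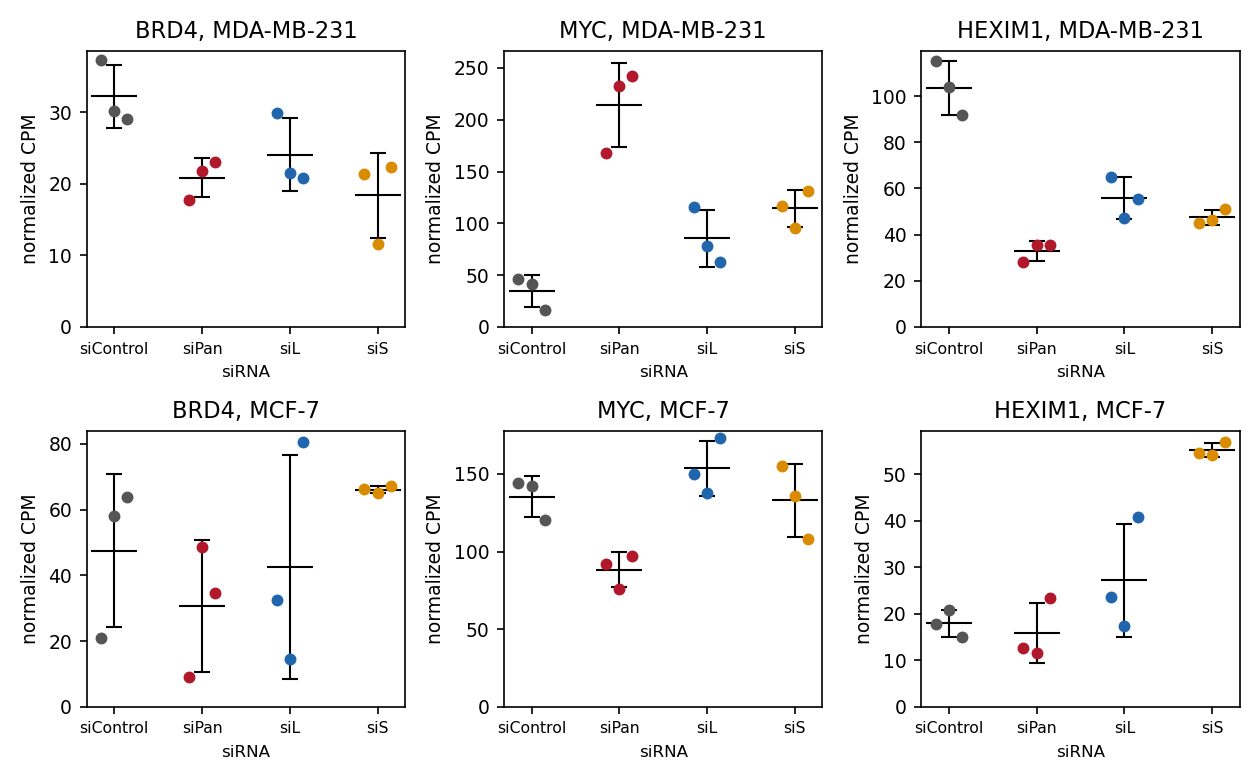
Normalized CPM of BRD4, MYC and HEXIM1 by siRNA in each line; points are libraries and bars the mean ± SD of 3. MYC after siPan in MDA-MB-231 had a mean of 215 CPM against 34.7 in siControl.

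The libraries of each line fell into 2 sets along the first principal component, which held 72.6% of the variance in MDA-MB-231 and 53.2% in MCF-7. Genes for small structural RNAs marked the sets in MCF-7, where RPPH1 and RMRP together took 2.72% to 4.7% of the signal in siControl 1, siPan 1, siL 1 and siL 2 and 0.244% to 0.531% in the other 8 libraries. The MTRNR2L genes, which resemble mitochondrial ribosomal RNA, took 9.64% to 11.8% there and 17.9% to 28.7% in the other 8. In MDA-MB-231 the first set held siControl 1, siControl 2, siPan 2, siPan 3, siL 1 and siL 2. Within the other 6 libraries of that line siControl 3 lay farthest out, with 1.81% of its signal from MALAT1, a nuclear noncoding RNA, against 0.23% and 0.194% in the other siControl libraries. Every siS library of both lines was in the second set, so the sets and siS overlap in part. A term for the sets, chosen after the data were seen, gives the alternative counts below.

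**Figure D2:**
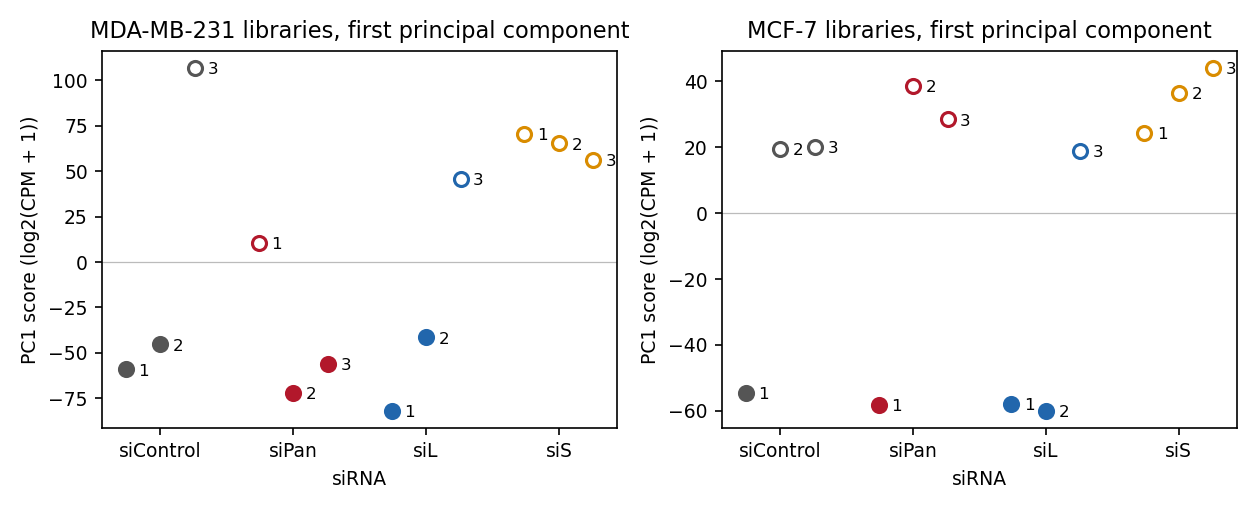
First principal component of log2(CPM + 1) per library by siRNA; filled points are the first set, open points the second, and numbers the replicates. siControl 3 of MDA-MB-231 lay at 106.9, beyond the other libraries of its line.

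The siPan comparison asks what the siRNA against all BRD4 transcripts does in MDA-MB-231. The largest rises were in SPTBN5, a spectrin (33.8 ± 9.04 against 2.78 ± 2.24 CPM, 3.44), and DMBT1, a secreted scavenger-receptor protein (48.6 ± 3.34 against 3.76 ± 0.707, 3.39, adjusted p = 0.000107). CDKN1A, the cell-cycle inhibitor p21, rose from 13.7 ± 8.94 to 107 ± 18.2 CPM (3.16, adjusted p = 0.00574), and the cytokine gene IL11 from 31.1 ± 9.85 to 244 ± 32.3 (2.97, adjusted p = 0.000902). CPA4 (3.12), SPNS2 (3.00), ADAMTS1 (2.93), OSGIN1 (2.93), SEMA7A (2.81) and SQSTM1 (2.71) were the other named rises. MYC rose from 34.7 ± 15.7 to 215 ± 40.2 CPM (2.70, adjusted p = 0.00289), and HEXIM1, an inhibitor of the elongation factor P-TEFb, fell from 104 ± 11.7 to 32.9 ± 4.31 (-1.63, adjusted p = 0.00179). The largest falls were in LDB3, a muscle Z-disc gene (0.541 ± 0.0139 against 13 ± 2.83 CPM, -3.16, adjusted p = 5.58e-05), BPI (-3.02), CEACAM1 (-2.83), SHISA3 (-2.81), SCIN (-2.77), SHISA2 (-2.62), MMD (-2.59) and GBP2 (-2.59). The tight-junction gene CLDN7 fell from 43.4 ± 11.7 to 6.69 ± 2.23 CPM and the integrin gene ITGB3 from 36.3 ± 4.77 to 5.40 ± 0.864, each by -2.54.

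Interferon-response genes fell as a group after siPan in MDA-MB-231: 13 of 38 fell and 0 rose (19 and 0 adjusted over the list alone), led by the antiviral genes IFIT1 (-2.35), IFIT2 (-2.05), OAS1 (-2.0) and IFI16 (-1.99), with a median of -1.08 (camera adjusted p = 4.56e-13, 0.000792 with an estimated correlation). Targets of YAP/TEAD, the transcription factors of the Hippo pathway, ranked high with 5 of 23 risen (8 adjusted over the list alone), among them CTGF from 151 ± 30.7 to 974 ± 43.3 CPM (2.70), ANKRD1 (1.99), GADD45B (1.60) and CYR61 (1.43). Their camera adjusted p was 5.17e-05, and 0.0189 with an estimated correlation. Cholesterol biosynthesis genes held too, at 4.49e-05 and 0.018, with INSIG1 (2.13) and IDI1 (1.5) risen of 26 (6 adjusted over the list alone). None of these 3 lists held with an estimated correlation in the fit with a library-set term, where the interferon list came to 0.0717.

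A further 11 lists passed camera after siPan in MDA-MB-231 only at the preset correlation. NRF2 targets, genes of the oxidative stress response, had 5 of 22 risen, led by OSGIN1, SQSTM1, FTL (2.67) and SRXN1 (1.81), with 3.32e-06 and adjusted p = 0.06 with an estimated correlation. FTL has near-identical copies, so its reads are uncertain. In the list of MYC targets and ribosome biogenesis MYC, ODC1 (2.13), RRP1B (0.92) and PNO1 (0.90) rose of 50 (0.00117, 0.0676 with an estimated correlation). G1/S genes rose in 5 of 58, led by CCNE1 (1.64), CDC6 (1.03), FEN1 (0.99) and ORC6 (0.93) (0.00102, 0.476 with an estimated correlation). The lists of immediate early genes, with DUSP1 (1.83), FOS (1.46) and SPRY2 (0.90) risen beside MYC, of hypoxia genes, with ANGPTL4 (2.0) and BNIP3 (1.36) risen and LOX (-1.59) fallen, and of luminal epithelial markers, with CLDN7, ELF3 (-2.24) and TJP3 (-1.36) fallen, each came to 0.717 with an estimated correlation. The autophagy list, with SQSTM1 alone risen and ATP6V0D1 next (1.09, adjusted p = 0.211), came to 0.717 as well. Ribosomal protein genes, RPL10 (1.22) and RPL18A (1.02) first, and histone genes, HIST1H1C (1.44) and HIST4H4 (1.31) first, had 0 called members, and came to 0.782 and 0.802 with an estimated correlation. Without siControl 3 the histone median went from 0.68 to 0.07, and the call ended.

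Of the ECM lists, 2 were called by camera after siPan in MDA-MB-231 at the preset correlation and are given first. Of 28 ECM proteases and inhibitors 6 rose and 1 fell (7 and 2 adjusted over the list alone), with ADAMTS1 from 11.5 ± 2.78 to 92.8 ± 10.3 CPM, ADAMTS6 (2.49), MMP1 (2.46) and ADAMTS12 (1.46) the largest. COL5A1 (2.04), COL7A1 (2.03) and COL24A1 (0.87) rose of 22 collagens. These camera adjusted p-values were 0.00656 and 0.0287, and 0.717 and 0.782 with an estimated correlation. Among 33 ECM glycoproteins, a list that camera did not call (adjusted p = 0.289), CTGF and CYR61 rose while fibronectin FN1 fell from 885 ± 271 to 255 ± 46.4 CPM (-1.75) and SLIT2 by -1.79. Of 14 integrins, not called either, ITGB2 rose (1.95) and ITGB3 fell. The adhesion gene ICAM1 fell by -2.51.

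In all, 578 genes were called after siPan in MDA-MB-231, 226 higher and 352 lower, and with the library-set term 3930, 2065 higher and 1865 lower. The count was 366, 304 and 979 without siControl 1, 2 and 3, and 280, 215 and 209 without siPan 1, 2 and 3. Of the 20 largest changes, 18 kept their call without each single library, while MMD lost it without 9 of them (adjusted p up to 0.151) and OSGIN1 without siPan 1, 2 or 3 (up to 0.0968). With only the 6 libraries compared, 17 of the 20 were not called. MYC and HEXIM1 kept theirs without each single library, at adjusted p-values up to 0.0207 and 0.0123, and lost them with only the 6 libraries compared (0.0975 and 0.0897). With the term the count was 1980 and 2304 without siPan 1 and siPan 2. DESeq2 called 1237 genes.

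**Figure D3:**
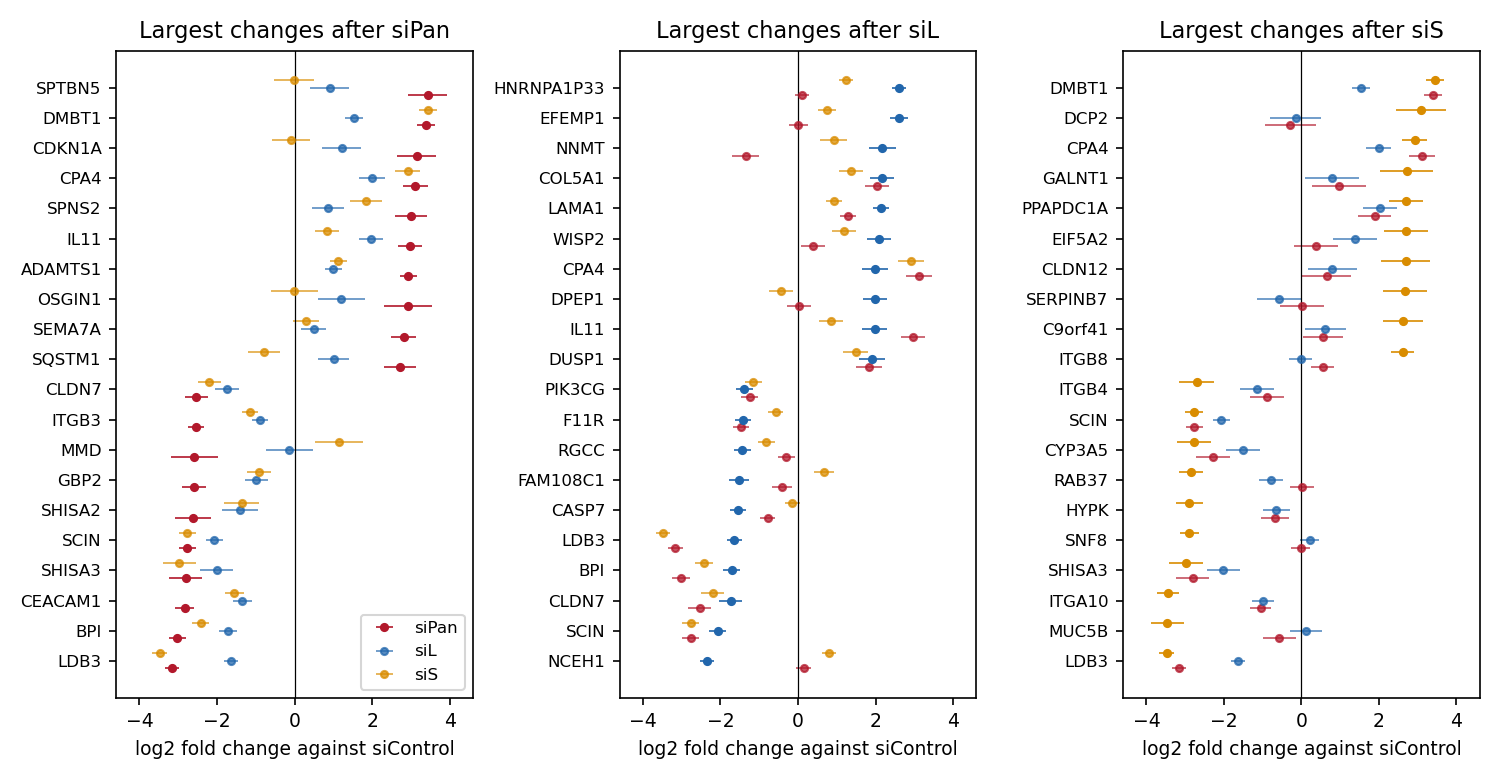
log2 fold change ± SE in MDA-MB-231 of the 20 genes with the largest changes after siPan, siL and siS (1 panel each); colours give the siRNA. DMBT1 rose by 3.39 after siPan and 3.44 after siS.

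The siL comparison asks what the siRNA against the long isoform does in MDA-MB-231. Loss of that isoform itself could not be measured. EFEMP1, which encodes the matrix protein fibulin-3, rose from 0.770 ± 0.412 to 9.80 ± 2.18 CPM (2.61, adjusted p = 0.00106), the laminin gene LAMA1 from 3.55 ± 0.691 to 19 ± 1.24 (2.15, adjusted p = 0.00181) and the collagen gene COL5A1 from 15.3 ± 5.31 to 70.7 ± 20.3 (2.16, adjusted p = 0.0196). HNRNPA1P33 (2.62), a pseudogene with near-identical copies, so that its reads are uncertain, NNMT (2.17), WISP2 (2.08), CPA4 (1.99), DPEP1 (1.98), IL11 (1.97) and DUSP1 (1.91) also rose. NCEH1, a cholesterol ester hydrolase gene, fell from 170 ± 25.3 to 32.6 ± 4.72 CPM (-2.34, adjusted p = 0.000441). SCIN (-2.07), CLDN7 (-1.74), BPI (-1.71), LDB3 (-1.64), the caspase gene CASP7 (-1.55), FAM108C1 (-1.52), RGCC (-1.43), F11R (-1.42) and PIK3CG (-1.38) fell as well. MYC at 85.5 ± 27.2 CPM (1.35, adjusted p = 0.175) and HEXIM1 at 55.9 ± 9.03 (-0.88, adjusted p = 0.0918) did not pass with limma. Both passed with DESeq2 (MYC at 0.0451, HEXIM1 at 0.00108) and with the library-set term (0.00299 and 0.00575), and HEXIM1 also without siControl 3 (0.0421); over all alternatives adjusted p ranged from 0.000234 to 0.998 for MYC and from 0.000612 to 0.981 for HEXIM1.

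Camera called 12 lists after siL in MDA-MB-231, and none held with an estimated correlation. G1/S genes, with CDC6 risen (1.05) and 13 of 58 risen adjusted over the list alone, had a median of 0.58 (adjusted p = 5.92e-11, 0.062 with an estimated correlation). YAP/TEAD targets, with ANKRD1 risen (1.57) and 10 of 23 adjusted over the list alone, had a median of 0.68 (5.92e-05, 0.0588 with an estimated correlation), and cholesterol genes, DHCR7 (1.35) and LSS (1.30) first, one of 0.42 (0.00291, 0.062 with an estimated correlation). COL5A1 was the called collagen (3 adjusted over the list alone) and LEPREL1 (1.12) the called collagen-modifying gene, in lists at 0.00082 and 0.0143 that each came to 0.577 with an estimated correlation. The interferon list (median -0.26, IFIT1 -1.11 and OAS1 -1.10 first) came to 0.0884 with an estimated correlation, and serpins (median -0.37) to 0.19. The TGF-beta, NRF2, histone, ribosomal protein and splicing lists were also called at the preset correlation alone, and without siControl 3 the splicing median turned from -0.19 to 0.04.

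The siL count in MDA-MB-231 was 72 genes, 40 higher and 32 lower, and 1197 with the library-set term (639 higher, 558 lower). Every library changed it by over 1.5 times: it was 16, 12 and 198 without siControl 1, 2 and 3, 36, 24 and 15 without siPan 1, 2 and 3, 18, 12 and 24 without siL 1, 2 and 3, and 33, 46 and 15 without siS 1, 2 and 3. EFEMP1, LAMA1, NCEH1 and the other 17 largest changes were kept with the term. Without each single library HNRNPA1P33, EFEMP1, LAMA1, NCEH1, SCIN and LDB3 kept their call and the other 14 lost it at least once (CPA4 and FAM108C1 at adjusted p up to 0.167), and with only the 6 libraries compared none of the 20 was called. With the replicate number as a term 15 genes were called, all of them among the 72, and 11 of the 20 largest changes were not (CLDN7 and FAM108C1 at adjusted p = 0.12). The count with the term was 511, 1805, 545 and 289 without siControl 2, siPan 1, siL 1 and siL 3. DESeq2 called 365 genes.

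The siS comparison asks the same for the siRNA against the short isoform, whose loss could not be measured either. DMBT1 rose most, to 50.5 ± 3.62 CPM (3.44, adjusted p = 9.1e-05), followed by the mRNA-decapping gene DCP2 (168 ± 53.5 against 23.3 ± 20.9 CPM, 3.08), CPA4 (2.92), GALNT1 (2.71), EIF5A2 (2.70), PPAPDC1A (2.70), CLDN12 (2.69), SERPINB7 (2.68) and C9orf41 (2.62). Of 14 integrins, a list that camera did not call (adjusted p = 0.525), 1 rose and 3 fell: ITGB8 rose from 0.649 ± 0.724 to 8.52 ± 1.06 CPM (2.61), while ITGA10 fell from 42.3 ± 11.8 to 2.88 ± 0.413 (-3.44, adjusted p = 0.000325), ITGB4 from 169 ± 86.2 to 22.5 ± 5.56 (-2.70) and ITGB3 by -1.15. LDB3 (-3.48), the mucin gene MUC5B (2.27 ± 0.213 against 40.0 ± 22.6 CPM, -3.45), SHISA3 (-2.98), RAB37 (-2.85), CYP3A5 (-2.78) and SCIN (-2.77) fell. SNF8, an endosomal sorting gene, fell from 132 ± 6.72 to 17 ± 0.718 CPM (-2.89), and HYPK, which overlaps a neighbouring gene so that its reads are uncertain, by -2.89. MYC rose to 115 ± 17.7 CPM (1.81, adjusted p = 0.0192) and HEXIM1 fell to 47.4 ± 3.19 (-1.11, adjusted p = 0.0113).

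Camera did not call the ECM glycoprotein, collagen, cholesterol or luminal lists after siS in MDA-MB-231 (adjusted p = 0.627, 0.866, 0.157 and 0.0835). Of 33 ECM glycoproteins 3 rose, IGFBP3 (2.13) most, and 3 fell, tenascin TNC (-2.03), EFEMP2 (-1.65) and LTBP1 (-1.42). Of 22 collagens COL5A1 (1.36) and COL12A1 (0.98) rose and COL13A1 (-1.73) and COL9A2 (-1.67) fell. Of 26 cholesterol genes 4 rose, MSMO1 (2.15), INSIG1 (1.49) and SQLE (1.37) most, and PMVK fell (-1.99). Of 18 luminal markers 4 fell, CLDN7 (-2.20), ELF3 (-2.15) and TJP3 (-1.41) most, and 1 rose. Single genes of other lists that were not called were the Wnt inhibitor gene DKK1 (2.14), the heat shock cochaperone gene BAG3 (-1.81) and the RNA-interference gene AGO1 (-1.33). Camera called G2/M genes (median 0.80, 2 of 64 risen, BUB1 1.14 and NCAPH 0.76, 1 adjusted over the list alone) at 1.87e-05 and DNA repair genes (2 of 35, MLH1 1.03 risen and XRCC6 -0.74 fallen) at 0.043, which came to 0.56 and 0.83 with an estimated correlation.

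After siS in MDA-MB-231 775 genes were called, 325 higher and 450 lower, and with the library-set term 2217, 1231 higher and 986 lower. The count was 234, 207 and 5560 without siControl 1, 2 and 3, 459 without siPan 3, 507 without siL 2, and 245, 271 and 234 without siS 1, 2 and 3; without siControl 3 all siControl libraries left were in the first set and all siS libraries in the second. With the term it was 1203, 3608 and 1223 without siControl 3, siPan 1 and siS 3. DMBT1, ITGA10 and the other 18 largest changes were kept with the term, and 14 of these 20 were kept without each single library. With only the 6 libraries compared, 17 of the 20 were not called (ITGA10 at adjusted p = 0.0546), and DMBT1, LDB3 and SNF8 were (0.0283 each). C9orf41, DCP2, EIF5A2 and SERPINB7 lost their call without siControl 1, siControl 2 or any siS library (DCP2 at adjusted p up to 0.101), and CLDN12 and GALNT1 also without siPan 2, siPan 3 or siL 2 (up to 0.137 and 0.17). MYC lost its call without siS 1, 2 or 3 (adjusted p up to 0.0839) and HEXIM1 without siControl 1, siControl 2 or siS 1 (up to 0.0618), and with only the 6 libraries compared they were at 0.13 and 0.117. DESeq2 called 1610 genes.

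The direct contrast of siL with siS shows where the 2 knockdowns differed, with values given as siL against siS. A difference can come from 1 knockdown alone, so it does not by itself show opposite effects. Against siControl, 2 genes were called in opposite directions after siL and siS, where independent calls would give 2.15. NCEH1 was lower with siL (32.6 ± 4.72 against 295 ± 22.5 CPM, -3.15, adjusted p = 6.45e-05), as were SERPINB7 (-3.25), DCP2 (-3.23), ATP11B (-3.13) and PPIP5K2 (-3.11). MUC5B (38.7 ± 10.9 against 2.27 ± 0.213 CPM, 3.57), SNF8 (157 ± 37.9 against 17 ± 0.718, 3.10), the ribosome-binding gene RRBP1 (305 ± 72.2 against 38.8 ± 2.59, 2.92), PLIN4 (2.83) and SPDEF (2.83) were higher. Of 33 ECM glycoproteins 4 were higher with siL, TNC (2.20), EFEMP1 (1.87) and FN1 (1.39) most, and 2 lower, IGFBP1 (-1.47) among them, and of 14 integrins 2 were higher, ITGA10 (2.45) most, and ITGB8 (-2.62) was lower. Camera called neither list (adjusted p = 0.0877 and 0.829), nor that of 14 basement membrane genes (0.344), in which LAMA1 was higher (1.23). With limma without further terms neither MYC (-0.45, adjusted p = 0.393) nor HEXIM1 (0.22, adjusted p = 0.434) differed past the threshold. MYC was lower with siL in the fit with the library-set term (-0.99, adjusted p = 0.0226) and with a surrogate variable (-0.76, 0.00127; range over all alternatives 0.00127 to 0.628), and HEXIM1 passed under none (0.27 to 0.816).

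Of the lists, collagens (COL9A2 2.49 and COL24A1 1.46 higher, 4 of 22 adjusted over the list alone) and NRF2 targets (SQSTM1 1.80, G6PD 1.73 and SRXN1 0.95 higher) ranked higher with siL than with siS in MDA-MB-231, and G2/M genes (BUB1 -1.08, CCNB1 -1.06) lower. Their camera adjusted p-values of 0.0261, 0.0125 and 0.00089 came to 0.929, 0.753 and 0.753 with an estimated correlation. The called genes numbered 942, 521 higher and 421 lower, and 1416 with the library-set term (722 higher, 694 lower). Without the term the count was 4179 without siControl 3, 571 and 456 without siPan 2 and 3, 225, 219 and 2501 without siL 1, 2 and 3, and 243, 283 and 214 without siS 1, 2 and 3. Without siL 3 most called genes were lower with siL (912 higher, 1589 lower). MUC5B, SNF8, NCEH1 and the other 7 named genes were kept with the term, which gave 2353, 184, 884 and 814 without siControl 3, siL 3, siS 1 and siS 3. Without the term DCP2, SPDEF, ATP11B and PPIP5K2 lost their call without any of siL 1, siL 2 and the siS libraries (PPIP5K2 at adjusted p up to 0.184), the last 3 also without siPan 3, and ATP11B and PPIP5K2 also without siControl 2 or siPan 2. DESeq2 called 2026 genes.

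Genes called after both siL and siS in MDA-MB-231 show how far the isoform knockdowns shared their effects. COL5A1, LAMA1 and CPA4 were higher after both, and LDB3, SCIN and CLDN7 lower after both. With the replicate number as a term, COL5A1, CPA4 and CLDN7 lost their siL call. Their limma adjusted p-values were then 0.0657, 0.0702 and 0.12, while LAMA1, LDB3 and SCIN kept the call. The count shared in the same direction went from 33 to 6. That term takes the same replicate effect in all 4 groups, also in siPan and siS, whose numbers did not all pair with siControl. It is therefore no paired test of siControl and siL alone. In all, 22 genes were higher and 11 lower after both, and 2 went in opposite directions, where independent calls would give 0.986, 1.09 and 2.15. Both contrasts use the same 3 siControl libraries. In 100 simulated draws of unchanged groups 0 shared calls arose. No gene was changed in those draws, so they cannot show how much shared controls add to the overlap of called genes. The shared count of 33 was 5, 5 and 135 without siControl 1, 2 and 3, 16, 9 and 7 without siPan 1, 2 and 3, 11, 6 and 12 without siL 1, 2 and 3, and 9, 15 and 7 without siS 1, 2 and 3. Across genes, which are not independent replicates, the fold changes had Pearson r = 0.0109, against 0.392 simulated for shared controls. With the library-set term r was 0.565, against 0.443 simulated. The draws shuffled all libraries of the line, so they did not keep the same-numbered pairs of siControl and siL. The simulated values therefore need not apply to these paired libraries. With the term 275 and 185 genes were higher and lower after both and 29 opposite. In MCF-7 0 genes were shared with limma or edgeR, and 5 in the same direction with DESeq2 (7 with a surrogate variable and 7 within the second library set).

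In MCF-7 the siPan comparison called 0 genes with limma and 0 with edgeR (1832 at an unadjusted p under 0.05), and DESeq2 called 207. MYC was at 88.4 ± 11.3 CPM against 135 ± 13.3 (-0.61, adjusted p = 0.287), and HEXIM1 at 15.9 ± 6.46 against 18 ± 2.88 (-0.22, adjusted p = 0.825). The fit with a library-set term called 858 genes, 380 higher and 478 lower (303 and 207 with a filter at 5 CPM, 229 and 543 with edgeR), and shows which genes moved once the sets were held apart. Targets of p53 were among the rises, with 9 of 29 called (14 risen and 1 fallen adjusted over the list alone): ZMAT3 (50.2 ± 14 against 21 ± 6.02 CPM, 1.22, adjusted p = 0.0024), the death receptor gene FAS (12.8 ± 1.44 against 5.17 ± 1.31, 1.17), TP53INP1 (1.05) and CDKN1A (119 ± 39.1 against 57.1 ± 18.6, 1.04, adjusted p = 0.00548). ENPP5 (1.41), ERO1L (1.25), ANKRD46 (1.19), ST8SIA6 (1.06), ABCB10 (1.02) and DENND1B (1.02) rose too, as did the cyclin gene CCND1 (0.92) and the cadherin gene CDH1 (0.89). Of 34 genes of the ATF4 amino acid response 13 fell (25 adjusted over the list alone), led by CHAC1 (-1.61), NUPR1 (15.6 ± 2.96 against 44.1 ± 1.91 CPM, -1.46), SLC6A9 (-1.16) and TRIB3 (-1.07). Of 25 cholesterol genes 4 rose, HMGCS1 (0.79), SQLE (0.64), IDI1 (0.57) and GGPS1 (0.47), and MYC (-0.61, adjusted p = 0.0367) and TIMP3 (-1.14) fell. The largest falls, ESRG (2.47 ± 1.85 against 24.7 ± 9.71 CPM, -3.01), TTN (-2.84), SPDYE7P (-2.59), POM121L10P (-2.44), VSTM4 (-2.28), HYDIN2 (-2.23), FDPSL2A (-2.19), NLRP12 (-2.19), KCNJ5 (-2.18) and C21orf62 (-2.15), were in genes of low level, several with near-identical copies. The 219 falling genes with at least 5 CPM in siControl followed the summed level of olfactory receptor genes, a measure of background. Over the 9 libraries without siPan Spearman rho was 0.733 (permutation p = 0.0315) and Pearson r 0.789 (permutation p = 0.00982). The 9 include the siControl libraries in which these genes were picked as high, so part of this correlation is built in.

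Camera gave adjusted p-values of 1.14e-05 for the p53 list, 2.3e-14 for the ATF4 list and 0.00191 for the cholesterol list after siPan in MCF-7 with the library-set term, and 0.363, 0.18 and 0.434 with an estimated correlation. Without the term it called 21 lists, with ATF4 genes (median -0.55, 9.63e-11), p53 targets (0.40, 0.000114), collagens (-0.76, 0.000114), ECM proteases (-0.48, 0.00143), ECM glycoproteins (-0.36, 0.00216) and cholesterol genes (0.30, 0.0024) among them, and each of these came to 0.333 with an estimated correlation. The siPan libraries listed 6354, 8054 and 7325 genes at 0, against 2675, 2948 and 2984 in siControl. With siL these were 5751, 4157 and 3335, and with siS 2943, 3916 and 6427. Whether the falling lists follow this difference in background was not tested. The count with the term rested on few libraries: 0, 20 and 21 without siControl 1, 2 and 3, 2436, 45 and 22 without siPan 1, 2 and 3, 1994 without siL 3, and 518 and 1395 without siS 2 and 3. Rescaling every library to the same total shifted the median fold change of all genes by -0.288.

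For siL in MCF-7, limma called 0 genes (712 at an unadjusted p under 0.05), edgeR 0 and DESeq2 17. The stress-response gene NUPR1 (-1.08, adjusted p = 0.879) and the lanosterol synthase gene LSS (1.31, adjusted p = 0.879) had large changes in called lists but did not pass. Camera called 9 lists, none with an estimated correlation, among them cholesterol genes (median 0.45, 3.53e-07, 0.344 with an estimated correlation), ATF4 genes (-0.21, 0.0014, 0.664 with an estimated correlation, 3 of 34 fallen adjusted over the list alone) and estrogen-responsive genes (0.15, 0.011, 0.284 with an estimated correlation). MYC (0.18, adjusted p = 0.894) and HEXIM1 (0.50, adjusted p = 0.879) did not pass. With the library-set term limma called 0 genes again (1697 at an unadjusted p under 0.05), 213 without siL 2, 27 and 15 without siPan 2 and siPan 1, 11 and 4 without siS 3 and siS 1, and 1 each without siControl 2 and siL 3.

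For siS in MCF-7, limma called 0 genes (1682 at an unadjusted p under 0.05; 2 without siL 3), edgeR 0 and DESeq2 280. HEXIM1 was at 55.2 ± 1.55 CPM against 18 ± 2.88 (1.58, adjusted p = 0.135). With the library-set term 524 genes were called, 403 higher and 121 lower, and HEXIM1 rose (1.43, adjusted p = 0.00569). Heat shock genes rose in 5 of 17 (6 adjusted over the list alone), with the chaperone gene HSP90AA1 from 563 ± 238 to 1990 ± 317 CPM (1.48), BAG3 (1.05), HSPA1A (0.91) and HSPA1B (0.87). Of 22 NRF2 targets 4 rose, FTH1 (1.10) and ME1 (0.96) most, and SLC7A11 fell (-0.75). Camera gave the heat shock and NRF2 lists 0.000121 and 0.000391, and 0.108 each with an estimated correlation. EPB41L2, a membrane-skeleton gene, rose from 18 ± 6.76 to 97.9 ± 10.5 CPM (1.96, adjusted p = 0.000272) and the drug-efflux gene ABCG2 from 18.3 ± 3.81 to 61.4 ± 14.5 (1.86, adjusted p = 0.000247). RPS16 (2.64), a gene with processed pseudogenes, BASP1 (1.93), CCDC86 (1.53), ATIC (1.42), LATS2 (1.37) and MAFB (1.35) rose, and RBM24 (-1.67), HSH2D (-1.27), PRSS23 (-1.23), PTGES (-1.23), TSTD1 (-1.20), POU2AF1 (-1.20), DRD1 (-1.18), IL20 (-1.16), GPX8 (-1.13) and NCR3LG1 (-1.10) fell. Without the term 13 lists were called and none held. The count with the term was 306, 96 and 14 without siControl 1, 2 and 3, 810 without siPan 1, and 95 and 296 without siS 2 and 3.

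Between siL and siS in MCF-7, 3 genes were called. The prostaglandin synthase gene PTGES (30.8 ± 8.18 against 3.91 ± 1.01 CPM, 2.68) and the sphingolipid regulator gene ORMDL3 (53.5 ± 8.46 against 18.3 ± 3.63, 1.5) were higher with siL, and the adhesion scaffold gene NEDD9 (10.7 ± 1.98 against 32.1 ± 2.47, -1.51) lower, each at adjusted p = 0.0491. HEXIM1, MYC and BRD4 did not pass with limma without further terms. Over all alternatives their adjusted p ranged from 0.0273 to 0.334, from 0.243 to 0.862 and from 0.102 to 0.856. G2/M genes, MKI67 (-1.78) and CENPF (-1.30) first, ranked lower with siL (median -0.39, 14 of 64 adjusted over the list alone, 3.69e-06, 0.413 with an estimated correlation), and heat shock genes did too (-0.42, 0.0296, 0.413 with an estimated correlation). The count was 1117 without siPan 1 and 993 without siL 3, and 0 without each of siControl 2, siControl 3, siPan 2, siPan 3, siL 1, siL 2, siS 1, siS 2 and siS 3. The limma p was under 0.05 unadjusted for 3729 genes, edgeR called 0 genes and DESeq2 1270. With the library-set term 241 were called, 104 higher and 137 lower, PTGES (2.15) again highest and ABCG2 (-1.84) and BASP1 (-1.87) among the lowest. That count was 37, 66 and 75 without siControl 1, 2 and 3, 914, 393 and 144 without siPan 1, 2 and 3, 100, 415 and 24 without siL 1, 2 and 3, and 14 and 70 without siS 2 and 3.

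**Figure D4:**
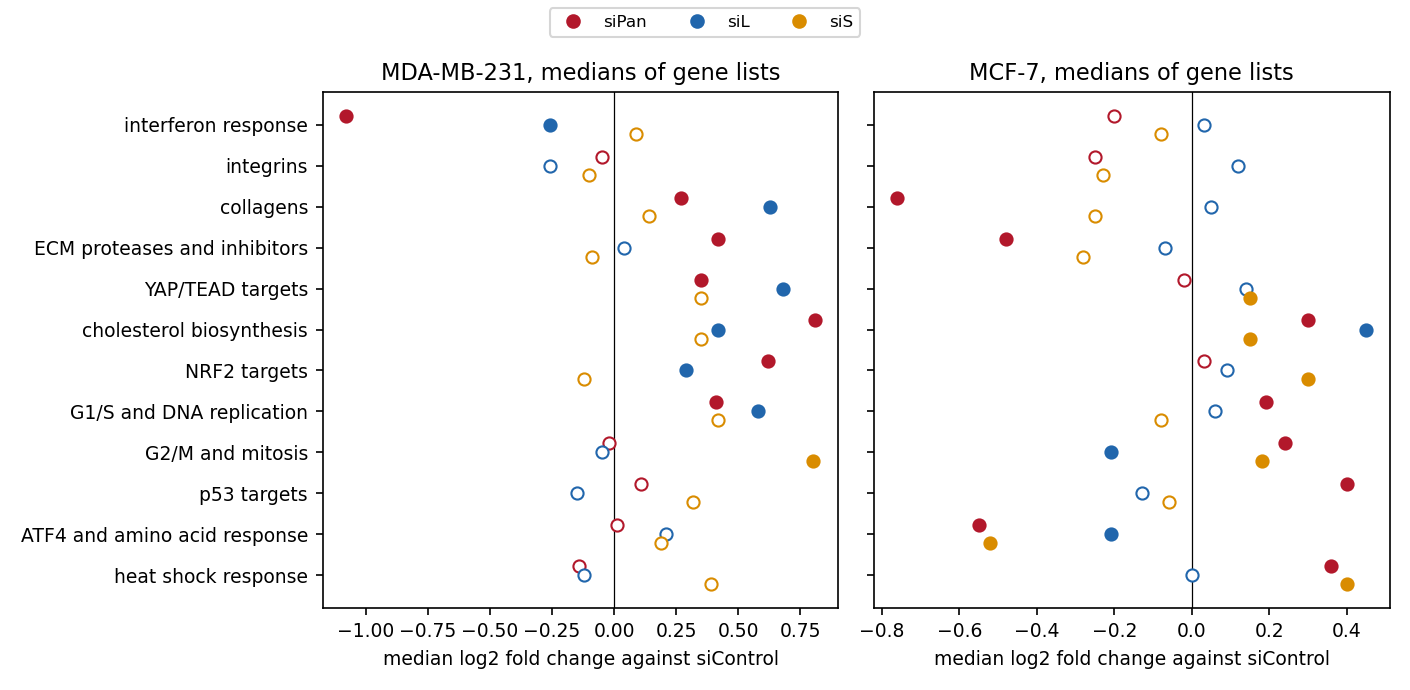
Median log2 fold change of 12 gene lists after siPan, siL and siS in each line; filled points passed camera at the preset correlation. The interferon list stood lowest in MDA-MB-231 after siPan, at -1.08.

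The lines were compared by their fold changes. MYC differed most after siPan, at 2.70 in MDA-MB-231 and -0.61 in MCF-7 (difference 3.31, SE 0.41, adjusted p = 7.55e-05). ODC1, a polyamine synthesis gene and MYC target, also moved apart (2.13 and -0.61, difference 2.74, adjusted p = 1.56e-05), and so did SQSTM1 (2.71 and -0.23, difference 2.95). Of 11914 genes 135 differed after siPan, 69 with the higher fold change in MDA-MB-231 and 66 with the lower (65 and 39 with each library rescaled to the same total, 34 and 53 with quantile normalization). That count was 52 and 62 without siPan 2 and 3 of MDA-MB-231, and 76, 79, 74, 75 and 238 without siControl 2, siControl 3, siPan 2, siPan 3 and siL 3 of MCF-7. After siS 193 genes differed, 54 higher and 139 lower (52 and 74 with each library rescaled to the same total, 1395 and 1027 without siControl 3 of MDA-MB-231, 2046 and 1373 with a surrogate variable), among them HEXIM1 (-1.11 and 1.58, difference -2.68, adjusted p = 0.000443) and BAG3 (-1.81 and 1.41, difference -3.22). Without siControl 1, 2 and 3 of MDA-MB-231 that count was 80, 92 and 2422, and without siS 1, 2 and 3 it was 107, 83 and 99. Without siControl 1, siControl 3 and siL 3 of MCF-7 it was 93, 95 and 339, and without siS 1, 2 and 3 it was 93, 87 and 118. After siL 8 genes differed, 6 higher and 2 lower, with EFEMP1 (2.61 and 0.16, difference 2.45, adjusted p = 0.00023) first. This count was 4, 4, 24, 5 and 2 without siControl 1, 2 and 3 and siL 1 and 2 of MDA-MB-231, and 3, 2, 3, 2, 3 and 13 without siControl 1, 2 and 3 and siL 1, 2 and 3 of MCF-7. Of the genes always named, HEXIM1 differed by -1.4 after siPan (limma adjusted p = 0.0672, 0.00114 with the library-set term). After siL MYC differed by 1.17 (0.773, 0.0194 with the term) and HEXIM1 by -1.38 (0.362, and -1.53 at 0.00413 with the term). BRD4 differed by -1.43 after siS (0.303, over all alternatives 0.0265 to 0.582). Across genes the fold changes of both lines had Pearson r = -0.103 after siPan, 0.434 after siL and 0.183 after siS, and with the library-set term -0.103, 0.248 and 0.0723. Of the genes called in MDA-MB-231, 423, 51 and 613 were also tested in MCF-7. Of these, 68.1%, 76.5% and 65.4% had the same direction in MCF-7. With the term the shares were 48%, 67.8% and 61.8%, of 3460, 1014 and 1915 genes.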

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

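Tests of the library sets, siControl 3, the spread between replicates and the fall in BRD4 were chosen only after the results were seen. So was every fit with the library-set term. The rules for the tests of background, of depth and of other splits were written before. The background test and some of the splits nevertheless use fits with that term, so these were not fixed before the results. The depth test concerns a difference in counts that the results had shown.

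Fold changes that differed between the lines past the threshold single out the genes below, with differences given as MDA-MB-231 minus MCF-7. After siPan the oncogene MYC differed by 3.31, the vesicle gene RAB3B by 3.28 (2.02 and -1.27), FTL by 3.01, the autophagy receptor SQSTM1 by 2.95 and ODC1 by 2.74. In the other direction the desmosome gene DSC2 differed by -2.47 (-2.28 and 0.19), the p53 regulator MDM2 by -2.45, MFSD6 by -2.44 (-1.61 and 0.83), the interferon-induced gene GBP2 by -2.44 (-2.59 and -0.15) and SHISA2 by -2.42 (-2.62 and -0.20). MDM2, at adjusted p = 0.0477, lost its call without 17 of the 24 libraries (up to 0.197), FTL and DSC2 without siPan 2 or siPan 3 of MDA-MB-231 (up to 0.0807 and 0.0759), and SHISA2 without any siPan library of MDA-MB-231 or siPan 3 of MCF-7 (up to 0.0799). The other 6 kept it without each single library.

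After siL the matrix gene EFEMP1 differed by 2.45, TUFT1 by 1.84 (1.70 and -0.14), ODC1 by 1.63 (0.65 and -0.97), CLDN7 by -2.22 (-1.74 and 0.48) and NCEH1 by -1.76 (-2.34 and -0.59). EFEMP1 alone kept its call without each single library. TUFT1, ODC1, CLDN7 and NCEH1, each at adjusted p = 0.0261, lost it without 12, 8, 10 and 6 of the 24 libraries, with adjusted p up to 0.166, 0.118, 0.158 and 0.0854.

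After siS the lipase cofactor gene ABHD5 differed by 3.00 (2.34 and -0.66), DCP2 by 2.84, RAB3B by 2.45, the endothelin gene EDN1 by 2.40 (2.39 and -0.01), C9orf41 by 2.20 and MYC by 1.84. HYPK differed by -3.53, RPS16 by -3.51 (-0.14 and 3.37), BAG3 by -3.22, CCDC92 by -2.96 (-1.88 and 1.08), ITGB4 by -2.79 (-2.70 and 0.08) and HEXIM1 by -2.68. HYPK overlaps a neighbouring gene and RPS16, like FTL above, has near-identical copies, so their reads are uncertain. C9orf41, RPS16 and DCP2 lost their call without 18, 14 and 11 of the 24 libraries (adjusted p up to 0.183, 0.165 and 0.164). RAB3B lost it without siControl 3 or siS 3 of MCF-7 (up to 0.0565), CCDC92 without siControl 1, siS 2 or siS 3 of MCF-7 (up to 0.0607), and MYC without any siS library of MDA-MB-231 or siS 3 of MCF-7 (up to 0.08). ABHD5, EDN1, HYPK, BAG3, ITGB4 and HEXIM1 kept it.

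For the 135 genes that differed after siPan, 5 of 100 joint splits of the libraries gave as many, the real one included, with 584 the highest of the others, so chance was not excluded. For the 8 after siL, 13 of 100 splits gave as many and the highest other was 4192, a number many times larger than the real count that points to a structure of the samples. For the 193 after siS, 3 of 100 did and the highest other was 291, a share under 0.05. These splits mix the siRNA labels within each line, so they stand for no siS effect in either line. The library sets are not kept in them either, so they cannot show whether a difference between the lines arose by chance.

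After siPan 578 genes, MYC and SQSTM1 among them, were called in MDA-MB-231 and 0 in MCF-7 with limma (1832 at an unadjusted p under 0.05; edgeR 0, DESeq2 207). A lower depth of the MCF-7 libraries does not account for this alone: with the MDA-MB-231 reads thinned to the MCF-7 depths, a median of 389.5 genes were still called over 10 draws (367 to 406). Nor does a larger spread, since the median standard error was 0.284 in MCF-7 and 0.353 in MDA-MB-231. A weaker fall of BRD4 in MCF-7 stays open, since BRD4 fell by 0.15 less in MDA-MB-231 with a standard error of 0.71 on that difference. A biological difference between the lines stays open and untested, and the library-set term gave 3930 and 858 called genes.

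In MDA-MB-231 every siS library lay in the second library set, so the changes of ITGA10, DMBT1 and the other genes called after siS could come from the sets. With the term for the sets 767 of the 775 called genes stayed called in the same direction. The median change went from 1.22 to 1.04, so a shift between 2 sets, as the term models it, did not remove most of it. The genes were picked in the same libraries, and the median standard error fell from 0.353 to 0.241, which favours staying called. siControl 3 was the only siControl library in the second set. The profile of siControl 3, which had the highest MALAT1 share of the 12 MDA-MB-231 libraries (1.81%) and the lowest share of ribosomal protein genes (5.95%), is a second candidate explanation. In the fit with the term but without siControl 3, 582 of the 775 stayed called, and 1203 genes were called in all. All 775 kept their direction, at a median of 1.07, though they had been picked against siControl 1 and 2 as well. That fit takes the shift between the sets from the siPan and siL libraries alone. Most of these changes thus did not need siControl 3, as far as that shift holds for siS. Without siControl 3 and without the term 5560 genes were called, but then the sets part siS and siControl completely. What the sets themselves come from was not tested, since the sample descriptions give no batch.

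In MCF-7 the falls after siPan in the fit with the library-set term, 478 genes led by ESRG and TTN, may come in part from a background of reads over silent genes. Olfactory receptor genes, which breast cells should not express, summed over 305 genes to 4.37, 3.96 and 7.09 CPM in the siPan libraries and to 17.4, 34.9 and 37.2 CPM in siControl. With siL they came to 4.83, 11.4 and 45.3 CPM and with siS to 23.6, 18.4 and 5.22. Over the 9 libraries without siPan, the 258 falling genes under 5 CPM in siControl followed this sum (Spearman rho 0.967, permutation p = 0.00016, adjusted 0.00032; Pearson r 0.95, permutation p = 5e-05, and 0.917 without the 2 farthest libraries). The 219 falling genes with at least 5 CPM did so less closely (rho 0.733, permutation p = 0.0315; r 0.789, permutation p = 0.00982, and 0.578 without the 2 farthest). Within the 6 of these libraries in the second set rho was 0.943 (permutation p = 0.0169) and 1 (permutation p = 0.0028). These genes were picked for being higher in siControl than in siPan, and the siControl libraries are among the 9. Their olfactory receptor sums were also higher than those of siPan, so part of the correlation is built in. Rising or unchanged genes were not set beside them, so the correlation does not single out background. Of the 380 rises 5 lay under 5 CPM. The calls rest on few libraries: the 858 genes became 0, 20 and 21 without siControl 1, 2 and 3, 45 and 22 without siPan 2 and 3, 2436 without siPan 1, 1994 without siL 3, and 518 and 1395 without siS 2 and 3 (the 0 with limma, 2442 at an unadjusted p under 0.05). No biological explanation of the falls was tested.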

How the results depend on the processing

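Fits with a library-set term, within a set, or with a surrogate variable were chosen only after the results were seen; the other alternatives were chosen before. The cause was not tested for any change below unless it is given. Counts are of called genes, and differences between lines are called by their siRNA.

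Both pseudocounts, TMM factors, robust limma and edgeR left every knockdown count against siControl within 1.5 times its value. Over the 464 gene results and 110 list results, the alternatives chosen before kept 9546 gene values and 2125 list values on their side of the threshold, with 1865 and 330 weaker, 112 and 65 stronger, and 0 and 7 reversed. The added ones kept 1468 and 210, with 12 and 47 weaker, 295 and 61 stronger, and 0 and 9 reversed.

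With only the 6 libraries compared, MDA-MB-231 gave 4 genes for siPan, 0 for siL (542 at an unadjusted p under 0.05; limma 72 over 12 libraries, edgeR 58, DESeq2 365) and 3 for siS, with 0 shared between siL and siS in the same direction and 0 in opposite directions. These fits have fewer libraries to estimate the spread from. MCF-7 gave 10 for siS and 339 for siL against siS, and the line differences 68 for siPan and 0 for siL (254 at an unadjusted p under 0.05).

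DESeq2 called 1237 genes for siPan, 365 for siL, 1610 for siS and 2026 for siL against siS in MDA-MB-231, and 207, 17, 280 and 1270 in MCF-7. It shared 154 in the same direction and 15 in opposite directions between siL and siS in MDA-MB-231, and 5 in the same direction in MCF-7. edgeR gave 0 for siL against siS in MCF-7 (3919 at an unadjusted p under 0.05; limma 3, DESeq2 1270).

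With the library-set term the counts were 3930, 1197, 2217 and 1416 in MDA-MB-231, in the same order, and 858, 524 and 241 for siPan, siS and siL against siS in MCF-7. siL and siS shared 460 in the same direction and 29 in opposite directions in MDA-MB-231, and the line differences were 3414, 334 and 1463 for siPan, siL and siS. The term with edgeR gave 3818, 1117, 2107 and 1433, then 772, 583 and 214, with 436 and 22 shared. The term with the filter at 5 CPM gave 3365, 1036 and 1879 for siPan, siL and siS, then 510, 614 and 295, with 390 and 25 shared and line differences of 2904, 318 and 1225. The term removed the spread between the sets: the median standard error fell from 0.353 to 0.209 for siPan in MDA-MB-231 and from 0.284 to 0.194 in MCF-7.

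A surrogate variable gave 4155, 2462, 6407 and 5852 in MDA-MB-231 and 957, 26, 799 and 1370 in MCF-7. It gave 1245 shared in the same and 248 in opposite directions in MDA-MB-231, 7 and 1 in MCF-7, and line differences of 1814, 538 and 3419. Within library set 1 siPan and siL gave 2134 and 450 in MDA-MB-231 and 3 and 12 in MCF-7. Within library set 2 siPan, siL and siS gave 5853, 2540 and 4805 in MDA-MB-231, with 1977 shared in the same and 7 in opposite directions, and 1080, 21 and 530 in MCF-7, with 1873 for siL against siS and 7 shared. Where a set held 1 library of a group, that library was assumed to vary like the others. In the second set of MDA-MB-231 this held for siControl, siPan and siL, so every comparison with siControl there rests on siControl 3. In MCF-7 it held for siControl 1 and siPan 1 in the first set and for siL 3 in the second.

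The replicate number as a block gave 15 for siL, 479 for siS and 531 for siL against siS in MDA-MB-231, with 6 shared in the same and 0 in opposite directions, and 2418 for siL against siS in MCF-7. Deviations from the group mean of libraries of the same number had correlations from -0.918 to 0.934. All 3 pairs exceeded 0.1 for siControl and siL of MDA-MB-231 (0.917, 0.535 and 0.934) and for siControl and siPan of MCF-7 (0.854, 0.538 and 0.528), where both libraries of each number lay in the same set, and in no other comparison. The block takes the same replicate effect in all 4 groups, also where the numbers did not pair. It is therefore no paired test of these 2 comparisons alone. For siL in MDA-MB-231, 17 named genes were no longer called with the block, COL5A1, CPA4, IL11 and CLDN7 among them. For siPan in MCF-7 it gave 0 genes with limma (2151 at an unadjusted p under 0.05; edgeR 0 and DESeq2 207 without the block), and the proteoglycan and chemokine lists were no longer called (0.0543 and 0.0555). Of the 72 genes called for siL 57 were lost with the block and 15 kept. No other named gene or list of these 2 comparisons changed its call. In the 3 other splits that part every pair the highest count was 0 in each of these comparisons, and with the library-set term 0 for siL and 1 for siPan; the split with 1865 genes for siL parts only some of the pairs.

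Every library rescaled to the same total gave 3 for siPan and 26 for siL against siS in MCF-7, 1 shared in opposite directions in MDA-MB-231, and a line difference of 126 for siS. It shifted the median fold change of all genes by -0.288 for siPan, -0.134 for siS and 0.156 for siL against siS in MCF-7 and by -0.116 for siPan in MDA-MB-231, where the share of higher calls fell from 39.1% to 25.3%. Quantile normalization gave 35 for siL against siS in MCF-7, 1 shared in opposite directions in MDA-MB-231 and a line difference of 87 for siPan. No filter gave 0 for siL against siS in MCF-7 (3989 at an unadjusted p under 0.05) and line differences of 341, 26 and 316, over more genes. The filter at 5 CPM gave line differences of 63 for siPan and 5 for siL, over fewer genes. A pseudocount of 0.25 gave 1 shared in opposite directions in MDA-MB-231, and 1 fit over all 24 libraries a line difference of 5 for siL.

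Which direction held more of the called genes depended on the setting. For siPan in MDA-MB-231 226 were higher and 352 lower, with the library-set term 2065 and 1865, and with the term and edgeR 1792 and 2026. For siS these were 325 and 450, 1231 and 986, and 921 and 1186. For siL they were 40 and 32, 639 and 558, and 547 and 570, and with quantile normalization 30 and 32. For siL against siS in MDA-MB-231 they were 521 and 421, with a surrogate variable 2551 and 3301, and without siL 3 912 and 1589. For the line differences of siS they were 54 and 139, with each library rescaled to the same total 52 and 74, without siControl 3 of MDA-MB-231 1395 and 1027, with a surrogate variable 2046 and 1373, and with the library-set term 700 and 763.

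The size of the largest changes depended on the setting for some genes, and for none of those below did the direction. Of 98 largest changes 19 had a log2 fold change that moved by over 1.5 times in some alternative. After siS in MDA-MB-231, CYP3A5 (-2.78) went from -5.60 with the library-set term and edgeR to -2.13 with a pseudocount of 2, and LDB3 (-3.48) from -5.80 with DESeq2 to -2.73 with that pseudocount. GALNT1 (2.71), CLDN12 and EIF5A2 (2.70) went to 1.51, 1.54 and 1.78 with the term (the first 2 with edgeR) and to 3.39, 3.45 and 3.35 without siControl 3. CEACAM1 after siPan (-2.83) went from -4.67 with edgeR to -2.17, and WISP2 after siL (2.08) from 1.56 to 3.24. For siL against siS, PLIN4 (2.83) went from 2.16 to 4.80 and PPIP5K2 (-3.11) from -3.84 to -1.65. For the line differences of siS, RPS16 (-3.51) went from -4.26 to -2.29.

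Leaving out each library in turn gave, in MDA-MB-231, 209 to 979 genes for siPan, 12 to 198 for siL, 207 to 5560 for siS and 214 to 4179 for siL against siS, and with the library-set term 1980 to 4230, 289 to 1805, 1203 to 3608 and 184 to 2353. In MCF-7 it gave 0 to 0 for siPan and for siL, 0 to 2 for siS and 0 to 1117 for siL against siS, and with the term 0 to 2436, 0 to 213, 14 to 810 and 14 to 914. Line differences ranged from 52 to 238 for siPan, 2 to 24 for siL and 80 to 2422 for siS. Shared calls of siL and siS in MDA-MB-231 ranged from 5 to 135 in the same and 0 to 7 in opposite directions, and in MCF-7 from 0 to 0 in both. The other counts with the term that moved past 1.5 times, in MDA-MB-231, were 2304 for siPan without siPan 2, 511 and 545 for siL without siControl 2 and siL 1, 1223 for siS without siS 3, and 884 and 814 for siL against siS without siS 1 and siS 3. In MCF-7 they were 20, 21, 45, 22, 1994, 518 and 1395 for siPan without siControl 2, siControl 3, siPan 2, siPan 3, siL 3, siS 2 and siS 3, and 1, 15, 27, 1, 4 and 11 for siL without siControl 2, siPan 1, siPan 2, siL 3, siS 1 and siS 3. For siS they were 306, 96, 95 and 296 without siControl 1, siControl 2, siS 2 and siS 3. For siL against siS they were 37, 66 and 75 without siControl 1, 2 and 3, 393 and 144 without siPan 2 and 3, 100, 415 and 24 without siL 1, 2 and 3, and 70 without siS 3. The highest MDA-MB-231 counts without the term came without siControl 3, and the 0 for siPan in MCF-7 with the term without siControl 1 (2442 at an unadjusted p under 0.05). No named gene past the threshold changed direction under any of the alternatives; 19 results of genes not past it did, all for BRD2, BRD3, BRD4, MYC and SIAE.

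The direction of the camera test, which sets a list against the other genes, turned for the lists below. Their medians turned with it except those of the histones, which fell but stayed above 0. In MDA-MB-231 the histone median after siPan went from 0.68 to 0.07 (up to 1.03 without siControl 1) and the splicing median after siL to 0.04 (-0.39 without siL 3), both without siControl 3. In MCF-7 after siPan the ribosomal protein median went to -0.07 with quantile normalization and -0.18 without siPan 1 (up to 0.5 without siControl 1), and the splicing median to -0.06 with quantile normalization. After siL in MCF-7 the histone median went from 0.5 to 0.02 with the library-set term, 0.01 with the term and the filter at 5 CPM, and 0.1 without siL 2 (1.1 without siL 3), and the ribosomal protein median to -0.13 in both fits with the term. After siS in MCF-7 the hypoxia median went to -0.18 without siS 1 (up to 0.71 without siS 3), and the ribosomal protein median to 0.18 in both fits with the term and 0.11 with a surrogate variable. Between siL and siS in MCF-7 the ribosomal protein median went to -0.28 in both fits with the term.

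In simulated libraries of this depth with library sets, limma without the term found 36.1% of 4-fold and 1.19% of 2-fold changes for siPan in MDA-MB-231 and 74.8% and 10.4% in MCF-7. At the same depth without sets it found 99.4% and 49% in MDA-MB-231 and 100% and 90.4% in MCF-7. Depth was not varied in these simulations, and changes were placed only in genes with a mean of at least 5 CPM. Changes of 1.5-fold were found in 4.78% and 24.8% even without sets. Thinning the MDA-MB-231 reads to the MCF-7 depths lowered the 578 genes called after siPan to a median of 389.5.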

Other observations

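The fits with the library-set term reported here, those over other splits among them, were chosen only after the results were seen. The counts over other splits without the term were chosen before.

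Genes shared between the siPan and the other knockdowns in MDA-MB-231 were not part of a planned comparison. CPA4, IL11, COL5A1 and DUSP1 were called higher and LDB3, BPI, SCIN and CLDN7 lower after both siPan and siL, among 16 genes higher and 15 lower in both and 2 opposite, where independent calls would give 0.686, 0.854 and 1.62. With the replicate number as a term CPA4, IL11, COL5A1, DUSP1 and CLDN7 lost their siL call (limma adjusted p = 0.0657 to 0.12), while LDB3, BPI and SCIN kept it. DMBT1, CPA4 and MYC were higher and LDB3, SCIN, SHISA3 and HEXIM1 lower after both siPan and siS, among 62 higher, 100 lower and 12 opposite, against 5.57, 12 and 16.4 for independent calls. The same 3 siControl libraries serve all these contrasts, and 100 simulated draws of unchanged groups gave 0 shared calls. With no gene changed, those draws cannot show how much shared controls add to the overlap of called genes. They shuffled the libraries and kept neither same-numbered pairs nor library sets. Across genes the covariance of the siPan and siL fold changes was 0.19 against 0.128 simulated, and that of siPan and siS -0.000766 against 0.0972, with Pearson r = -0.00167 against 0.329. With the library-set term the siPan and siS covariance was 0.215 against 0.0381. In MCF-7 with the library-set term 56 genes were higher and 23 lower after both siPan and siS and 3 opposite, against 11.1, 4.19 and 17.3, with a mean of 15.8 and a maximum of 971 shared calls simulated.

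In the fit with the library-set term both lines were called together for some genes. After siPan 57 genes rose in both lines and 65 fell in both, 28 rose in MDA-MB-231 and fell in MCF-7, and 17 did the reverse, where independent calls would give 57.8, 35.2, 42.6 and 47.7. CDKN1A was among the genes that rose in both lines. After siS these counts were 66, 33, 5 and 24 against 34.7, 7.34, 9.22 and 27.6.

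Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05, so only the counts are given. For siPan in MDA-MB-231 the real count was 578 and the highest of the other splits 0, with the library-set term 3930 and 0, and in each case 1 of the 10 splits gave as many. After siS these were 775 and 0, and 2217 and 0, and between siL and siS 942 and 0, and 1416 and 0, again with 1 of 10. For siL in MDA-MB-231 the real count of 72 was exceeded by 1865 in the split of siControl 1, siControl 2 and siL 1 against the rest, so that 2 of 10 gave as many, while with the term the counts were 1197 and 0. That split follows the library sets in part, with siL 2 alone on the other side, and points to a structure of the samples. In MCF-7 the real count and the highest other were 0 and 0 for siPan and for siS, and for siL 0 and 3468, the last in the split of siControl 1, siL 1 and siL 2 against the rest, which is the split into the library sets, so that 10 of 10 splits gave as many in each. With the term they were 858 and 1 for siPan, 0 and 0 for siL (10 of 10), 524 and 0 for siS, and 241 and 1 between siL and siS, where the count without the term was 3 and 0.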
